A study of Arabidopsis thaliana with 36 samples.

How the data were processed

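Total RNA was sequenced from roots and rosettes (labelled shoot) of 42 day-old Arabidopsis thaliana plants of 6 genotypes, with 3 biological replicates of each genotype in each tissue and 36 libraries in all. The genotypes are the wild types Col-0 and Col-4 and the mutants nlp2-2, nlp2-3, nlp7-1 and nlp2-3 nlp7-1, in which the genes of the transcription factors NLP2 or NLP7, or both, are disrupted. Per the labels, seeds were stratified for 3 days and plants grew in sand culture with 5 mM nitrate, described there as non-limiting, with 8 h of light and 16 h of dark at 21 and 18 °C. RNA was prepared with a column kit that included a DNase step, libraries were made with the NEBNext Ultra RNA kit, and a sequencing company read them on an Illumina instrument. The ecotype tag reads Col-0 for every sample, and the sample titles, descriptions and column names tell Col-4 from Col-0.

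The authors deposited 2 tables with the same 34218 features, of which 32833 are gene loci and 1385 are RNA features of another annotation. The deposited count table holds raw counts per gene, as whole numbers with 1 column per library. The deposited FPKM table holds FPKM, fragments scaled to transcript length and library size. The FPKM values were checked on 11125 genes with over 100 counts in every library and follow from the counts, the sum of each column and 1 length per gene. The submitters' processing notes name HISAT2, HTSeq and the TAIR10 assembly, and the sources used here give no version, gene model set, filter or strand setting. Counts of antisense or overlapping genes and of close paralogs are therefore uncertain. The gene names come from a reference table for TAIR10.1, in which 32548 of the locus codes were found. Since the build differs by name from TAIR10, no coordinates are printed, and the table was used only for names and for which genes lie near one another.

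Root libraries held 1.84e+07 to 2.85e+07 counted fragments and shoot libraries 1.82e+07 to 3.17e+07. The 10 most abundant genes took 3.15 to 3.53% of the counts in roots and 8.32 to 9.92% in shoots. At these depths 22235 to 23060 features were detected per root library and 20617 to 21732 per shoot library. Values called CPM, scaled to 1e+06 counts per library, are counts over the library total after scaling by the trimmed mean of M values (TMM), given with their standard deviation (SD) and n = 3. The spread between replicates exceeded counting error, with 2.77 to 16.4 times the variance that counting alone gives over the groups, so the replicates and not the depth limit most comparisons.

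Each comparison was tested with edgeR 4.0.16 in R 4.3.3. Counts were filtered with filterByExpr (minimum count 10, minimum total 15) and scaled with TMM, and a robust quasi-likelihood (QL) model with 1 mean per genotype was fitted to the 18 libraries of a tissue. The F test was two-sided, and the Benjamini-Hochberg (BH) method adjusted p over all genes tested: 20486 in roots, 19137 in shoots and 21554 in the fit of both tissues. A gene was called when its adjusted p was under 0.05. The standard error (SE) of a log2 fold change is its size over the square root of F. Roots and shoots were fitted apart, with 12 residual degrees of freedom each. Differences between the tissues in the effect of a mutation were tested in a fit of all 36 libraries with 24. The p-values measure the spread between these biological replicates.

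The main comparisons set nlp2-2 against Col-4, and nlp2-3, nlp7-1 and nlp2-3 nlp7-1 against Col-0, in each tissue. The labels do not say which wild type is the parent of which mutant, so nlp2-2 was also compared with Col-0, and Col-4 with Col-0. The double mutant was compared with each of its single mutants, and the interaction of both mutations was tested. For the main comparisons the genes named are NLP2 and NLP7, up to 6 genes in each direction with the largest change among called genes with a symbol, a mean of at least 5 CPM and no overlap between groups, and up to 8 called genes of nitrate and nitrogen metabolism. NRT2.1, NIA1, NIA2, NIR1 and NPF6.3/NRT1.1 are named whether called or not, and so are up to 4 called members of each other list that passed its test or had at least 4 called members. Up to 3 genes in each direction are named for the other comparisons. Where fewer than 10 genes were called all may be named. Genes outside this rule are named as such.

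A set of 27 gene lists with 401 genes, all present in the table, was written from general knowledge of plant genes. They cover nitrate transport, nitrogen assimilation, nitrate signalling, ammonium transport, pentose phosphate and reductant, organic acid metabolism, sucrose and starch metabolism, low energy response, senescence, phosphate starvation, sulfur deficiency, iron deficiency, hypoxia, cytokinin, flowering, glucosinolate, anthocyanin, salicylate defence, jasmonate, abscisic acid with cold and drought, heat shock, circadian clock, photosynthesis, root hair, root endodermis and suberin, xylem, and cell cycle. The 9 NLP family members were read gene by gene. Lists were tested against all other genes with limma 3.58.1 camera on voom values with a preset correlation of 0.01 between genes. The test was repeated with the correlation estimated for each list, and BH adjustment was over the lists of a comparison. Of 89 list calls with the preset value, 7 held with the estimated correlation, so most list calls rest on genes of 1 list varying almost independently.

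The samples, comparisons, rule for names, gene lists and alternatives were fixed before the data were examined. The alternatives were scaling by relative log expression (RLE), no filter on low counts, the DESeq2 1.42.0 Wald test, limma-trend on log2(FPKM + 1), a fit of only the groups compared, replicate number as a block, and leaving out each library in turn. Leaving out the 2 libraries of each tissue farthest from their group means was chosen after seeing the data. Replicate numbers from the titles were not used to pair libraries in the main tests. After group means were removed, libraries of the same number correlated over 0.1 for every number in 2 of 16 comparisons of a pair of groups. That limit serves only to describe them. Between nlp2-2 and Col-4 roots the correlations across genes were 0.109 to 0.184, and between nlp2-3 and Col-0 roots 0.235 to 0.381. With a replicate block those comparisons called 1758 and 1711 genes, against 1458 and 1401 in the main tests. Between Col-4 and Col-0 shoots, at 0.0928 to 0.143, a block gave 622 genes against 152. Scaling by RLE or by DESeq2 moved the median log2 fold change of all genes by between -0.02 and 0.01.

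The procedure was tested on simulated data with the means and spreads of these libraries. In simulated nlp2-3 against Col-0 roots it recovered 61.2% of genes changed 1.5-fold, 85.1% of those changed 2-fold and 93.9% of those changed 3-fold. It made 10 false calls of unchanged genes there, in a fit of 20334 genes, changed ones included. In simulated shoots it recovered 59.7%, 83.6% and 89.4%, with 5 false calls in a fit of 18962. A list shifted on purpose was called in both tissues, and no other list was called. The simulated genes varied independently, so this does not test the list calls where genes of 1 list vary together. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. No library was left out of the results below.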

Results

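RNA from roots and shoots of 6 Arabidopsis genotypes was counted per gene in 36 libraries, 3 biological replicates for each genotype and tissue. NLP2 and NLP7 are transcription factors of the NIN-like protein family, whose members bind nitrate-responsive promoters, and the series asks how the transcriptome of their mutants differs from that of wild type. Root libraries held 1.84e+07 to 2.85e+07 counted fragments and shoot libraries 1.82e+07 to 3.17e+07. Fold changes are log2 values of the first genotype over the second, with their standard error from edgeR and n = 3 libraries per group.

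The transcripts of the mutated genes were read first, to see how much of each remained. In roots NLP2 stood at 55.4 ± 1.5 CPM (SD, n = 3) in Col-4 and 18.1 ± 4.3 in nlp2-2, and at 65.8 ± 0.78 in Col-0 and 36.8 ± 3.1 in nlp2-3. In shoots it stood at 41.5 ± 2.8 in Col-4, 28.8 ± 1.3 in nlp2-2, 53.7 ± 1.2 in Col-0 and 16.1 ± 0.69 in nlp2-3. The log2 fold change of NLP2 was -1.62 ± 0.12 in nlp2-2 roots, -0.53 ± 0.07 in nlp2-2 shoots, -0.84 ± 0.11 in nlp2-3 roots and -1.74 ± 0.07 in nlp2-3 shoots, each called. NLP7 fell from 103 ± 10 CPM in Col-0 roots to 35.1 ± 2.7 in nlp7-1 and 41.3 ± 0.25 in the double mutant. In shoots it fell from 48.6 ± 0.42 to 21.2 ± 2.5 and 24 ± 2.1. Counts of a disrupted gene can include transcripts that no longer encode the full protein, and the position of the insertions is not given in the labels.

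In nlp7-1 roots NLP2 rose to 93.6 ± 6.7 CPM (log2 fold change 0.51 ± 0.11, edgeR QL with BH adjusted p = 0.0065), while in nlp7-1 shoots it stood at 53.5 ± 2.2 CPM (-0.01, adjusted p = 0.97). The double mutant held 49.4 ± 3.7 CPM of NLP2 in roots, against 36.8 in nlp2-3, and 9.06 ± 0.55 CPM in shoots. The root difference (0.42, adjusted p = 0.0298) lost its call without any 1 of the nlp2-3 replicates, double mutant replicate 1 or 2, or the 2 farthest libraries (adjusted p up to 0.129). NLP7 was not called in nlp2-2 or nlp2-3 in either tissue. Other family members moved in roots: NLP4 rose by 0.58, 0.64, 0.57 and 0.98 and NLP5 by 0.38, 0.50, 0.48 and 0.95 log2 units in nlp2-2, nlp2-3, nlp7-1 and the double mutant. NLP3 rose in roots of nlp7-1 (0.91) and of the double mutant (0.76), NLP6 in the same 2 (0.33 and 0.38) and NLP8 in the double mutant alone (0.96). In shoots NLP3 fell in nlp2-3 (-1.01 ± 0.18) and rose in nlp7-1 (0.80 ± 0.16). It was not called in shoots of nlp2-2 (-0.16, adjusted p = 0.78) or of the double mutant (-0.15, adjusted p = 0.54). NLP1 fell in shoots of the double mutant (-0.35 ± 0.11), a call that ended without Col-0 replicate 2 or 3 or double mutant replicate 1 (adjusted p up to 0.134) and by limma on log2(FPKM + 1) (0.0771). It stood at 15.4 ± 1.9 CPM there and 19.7 ± 2.5 in Col-0 shoots, but Col-4 shoots held 15.5 ± 1.8, near the double mutant.

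**Figure D1:**
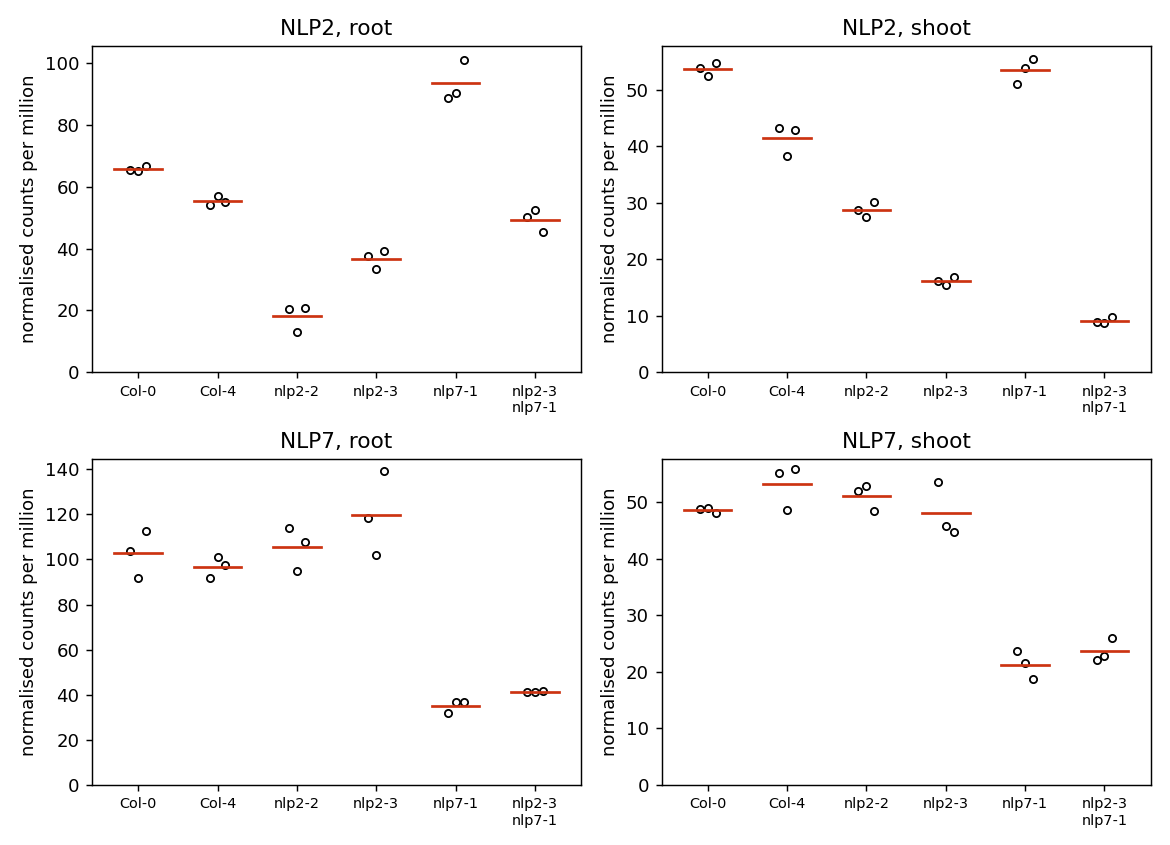
Normalised CPM of NLP2 and NLP7 in each of the 36 libraries (open circles) with the mean of each genotype (red line), roots on the left and shoots on the right. NLP2 in nlp2-2 and nlp2-3 lies below both wild types in each tissue, and NLP2 in nlp7-1 roots averages 93.6 against 65.8 in Col-0.

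The comparison of nlp2-2 with Col-4 roots asks what the loss of NLP2 does to the root when nitrate is ample. Nitrate transport genes went both ways, 9 of 23 lower and 2 higher, and the list did not pass (adjusted p = 0.0651, adjusted p = 0.633 with an estimated correlation). NPF6.3/NRT1.1, the dual-affinity nitrate transporter and sensor, changed by -0.94 ± 0.09, and NPF7.3/NRT1.5, which loads nitrate into the xylem, by -1.05 ± 0.09. The nitrite reductase gene NIR1 changed by -0.55 ± 0.10 and NRT3.1, the partner of the high-affinity carriers, by -0.81 ± 0.14. The urea carrier DUR3 (2.21 ± 0.11, from 20.1 ± 2.5 to 93 ± 8.8 CPM), the high-affinity nitrate carriers NRT2.4 (1.07 ± 0.14) and NRT2.5 (1.58 ± 0.23), and the cytosolic glutamine synthetases GLN1;4 (1.38 ± 0.14) and GLN1;1 (0.51 ± 0.07) rose. NRT2.1, the main inducible carrier, stood at 0.08 (adjusted p = 0.79) and the nitrate reductase gene NIA2 at -0.04 (adjusted p = 0.90). The other nitrate reductase gene, NIA1, changed by -0.50 ± 0.12, a call that ended without Col-4 replicate 1 or 2 or nlp2-2 replicate 2 or 3 (adjusted p up to 0.107).

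Beyond nitrogen, all 11 measured hypoxia genes fell in nlp2-2 roots, and all 11 adjusted over the list alone. The nonsymbiotic haemoglobin GLB1 changed by -0.95 ± 0.13 and the ethylene response factor HRE2 by -1.37 ± 0.20, and the list had a median of -0.81 (camera adjusted p = 1.23e-16, adjusted p = 0.0875 with an estimated correlation). Of 17 phosphate starvation genes 8 fell and none rose (9 adjusted over the list alone), with the phosphatase PAP17 at -1.45 ± 0.15 and the noncoding RNA IPS1 at -2.82 ± 0.46; this list kept its call with an estimated correlation (adjusted p = 0.0345). The sucrose synthases SUS1 (-0.91 ± 0.12) and SUS4 (-0.91 ± 0.15), both also on the hypoxia list, the cytokinin synthesis genes IPT3 (-0.93 ± 0.11) and CYP735A1 (-0.85 ± 0.13), and the phosphoenolpyruvate carboxylase PPC3 (-0.63 ± 0.08) fell. The ammonium carrier AMT1;2 (0.80 ± 0.14) and the subunits NF-YA2 (1.44 ± 0.09) and NF-YA10 (1.71 ± 0.13) of a CCAAT-binding factor rose. The largest falls among the genes named were in the amino acid exporter UMAMIT36 (-3.74 ± 0.30), the beta-amylase BAM5 (-3.58 ± 0.28) and the zinc pump HMA2 (-2.83 ± 0.25).

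In all, 1458 genes or 7.12% of those tested were called in nlp2-2 roots, 656 higher and 802 lower, and 234 of them changed at least 2-fold. The number was 907 without Col-4 replicate 3, 931 without nlp2-2 replicate 1 and 846 without nlp2-2 replicate 2. Against Col-0 in place of Col-4, 1762 genes were called. That number was 1140 when only the groups compared were fitted and 987 without nlp2-2 replicate 2. Both wild types gave the same direction for 1101 genes and opposite directions for none. Both comparisons use the same nlp2-2 libraries, so opposite calls were unlikely and the agreement is no independent repeat.

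The second NLP2 allele, nlp2-3, was compared with Col-0 roots. The nitrate genes moved as in nlp2-2: NPF6.3/NRT1.1 changed by -0.92 ± 0.09, NPF7.3/NRT1.5 by -1.08 ± 0.09, NRT3.1 by -0.91 ± 0.14 and NIA1 by -0.66 ± 0.13. NIR1 changed by -0.49 ± 0.10, a call that ended when only the groups compared were fitted (adjusted p = 0.0650). DUR3 rose by 2.03 ± 0.11, GLN1;4 by 1.38 ± 0.14, NRT2.4 by 0.88 ± 0.13 and NRT2.5 by 1.19 ± 0.23, and NRT2.1 (-0.09, adjusted p = 0.73) and NIA2 (-0.09, adjusted p = 0.74) were not called. All 11 hypoxia genes fell again, also adjusted over the list alone, with GLB1 at -0.88 ± 0.13 and a list median of -0.70 (adjusted p = 3.57e-14, adjusted p = 0.194 with an estimated correlation). Phosphate starvation genes fell in 8 of 17 cases (10 adjusted over the list alone), PAP17 by -1.33 ± 0.15 and IPS1 by -2.96 ± 0.44, and the list kept its call with an estimated correlation (adjusted p = 0.0168).

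The hypoxia list members SUS1 (-0.83 ± 0.12) and SUS4 (-0.84 ± 0.15), and IPT3 (-0.70 ± 0.11), PPC3 (-0.63 ± 0.08), UMAMIT36 (-3.45 ± 0.28) and HMA2 (-3.02 ± 0.26) also fell in nlp2-3 roots. Glucosinolate synthesis genes, which make sulfur-rich defence compounds, rose in 5 of 11 cases and fell in none (7 and 1 adjusted over the list alone), with CYP79B2 at 0.57 ± 0.07 and the list at adjusted p = 7.03e-05, or adjusted p = 0.274 with an estimated correlation. The myrosinase genes TGG1 and TGG2 rose by 4.02 ± 0.45 and 3.82 ± 0.45, TGG1 from 1.1 ± 0.34 to 18 ± 2.5 CPM. They are leaf genes, yet the photosynthesis list had a median of -0.45 in the same comparison. QQS fell by 4.21 ± 0.35 on the log2 scale, and the change of Col-4 over Col-0 roots was -5.32 ± 0.39, so QQS was high in Col-0 alone. A total of 1401 genes was called, 688 higher and 713 lower, 214 at least 2-fold. That number was 855 without nlp2-3 replicate 1, 905 without nlp2-3 replicate 3 and 659 when only the groups compared were fitted.

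Called genes of both alleles overlapped, although the alleles were tested against different wild types. In roots 892 genes were called in the same direction in nlp2-2 and nlp2-3, 391 higher and 501 lower, where independent lists of these sizes would share 22.0 and 27.9. The fold changes of all genes correlated at r = 0.571 across genes, which are not independent replicates, with a covariance of 0.0824 against a simulated 6.85e-05. Opposite directions were called for 3 genes. These comparisons share no library.

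Roots of nlp7-1 differed from Col-0 in the same nitrate genes and in others. NPF6.3/NRT1.1 changed by -1.07 ± 0.09, NPF7.3/NRT1.5 by -1.60 ± 0.10, NIA1 by -1.14 ± 0.13, NIR1 by -0.63 ± 0.10 and NRT3.1 by -1.32 ± 0.14, and NIA2 was not called (0.09, adjusted p = 0.68). NRT2.1 fell (-1.11 ± 0.12, from 1307 ± 209 to 606 ± 19 CPM), and NRT2.5 rose by 4.61 ± 0.20, from 1.23 ± 0.26 to 30.4 ± 5.3 CPM. Among regulators of the nitrate response LBD39 (-1.41 ± 0.07), BT1 (-1.70 ± 0.14) and NAC4 (-2.11 ± 0.17) fell, and 10 of 27 nitrate signalling genes fell with none higher (12 lower and 2 higher adjusted over the list alone; adjusted p = 5.81e-07, adjusted p = 0.246 with an estimated correlation). DUR3 (2.07 ± 0.11), GLN1;4 (1.73 ± 0.14), the glutamate dehydrogenase GDH3 (1.65 ± 0.14) and the ammonium carrier AMT1;5 (2.67 ± 0.53) rose. The potassium channel SKOR, which releases potassium into the xylem, fell by 2.57 ± 0.16 on the log2 scale.

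Phosphate genes fell in nlp7-1 roots as well: 8 of 17 list members were lower (10 adjusted over the list alone), with the transporter PHO1;H1 at -1.86 ± 0.13, PHO1 at -0.66 ± 0.08 and the uptake carrier PHT1;3 at -2.49 ± 0.37, and the list kept its call (adjusted p = 2e-07, adjusted p = 0.0401 with an estimated correlation). Of 11 glucosinolate genes 10 rose (10 adjusted over the list alone), among them CYP79B2 (0.82 ± 0.07) and CYP79F2 (0.65 ± 0.08), with adjusted p = 1.49e-13 or adjusted p = 0.114 with an estimated correlation. Hypoxia genes fell in 8 of 11 cases (9 adjusted over the list alone), with GLB1 at -0.65 ± 0.12, a list median of -0.53 and adjusted p = 7.08e-09, or adjusted p = 0.221 with an estimated correlation. The trehalose phosphate synthase genes TPS8 (-0.91 ± 0.17), TPS9 (-0.70 ± 0.09) and TPS10 (-1.21 ± 0.14) fell. In all 1627 genes were called, 921 higher and 706 lower, 254 at least 2-fold; the number was 1061 without nlp7-1 replicate 2 and 1010 without nlp7-1 replicate 3.

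The double mutant nlp2-3 nlp7-1 shows what the root loses when both factors are disrupted. Several nitrate genes fell, NIA1 by -2.58 ± 0.13 on the log2 scale, NPF7.3/NRT1.5 by -2.14 ± 0.10, NRT3.1 by -1.98 ± 0.14, NRT2.1 by -1.51 ± 0.12, NPF6.3/NRT1.1 by -1.36 ± 0.09, NIR1 by -1.08 ± 0.10 and NIA2 by -0.54 ± 0.11. Regulators of the nitrate response fell with them, BT1 by -2.17 ± 0.15, LBD39 by -1.46 ± 0.07 and TGA1 by -1.02 ± 0.07, and 13 of 27 nitrate signalling genes were lower and 4 higher (15 and 4 adjusted over the list alone; adjusted p = 3.66e-06, adjusted p = 0.234 with an estimated correlation). Of 17 nitrogen assimilation genes 11 were lower and 4 higher, also adjusted over the list alone (adjusted p = 0.00596, adjusted p = 0.271 with an estimated correlation). NRT2.5 rose by 4.66 ± 0.20, DUR3 by 3.01 ± 0.11 (from 21.2 ± 0.11 to 170 ± 26 CPM) and AMT1;5 by 3.34 ± 0.51, and all 4 measured ammonium carriers were called higher, though AMT2;1 (0.18) and AMT1;3 (0.44) not in every setting (adjusted p up to 0.224 and 0.128).

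All 11 hypoxia genes fell in double mutant roots, also adjusted over the list alone, with a median of -2.12 against -0.81 in nlp2-2, -0.70 in nlp2-3 and -0.53 in nlp7-1. The alcohol dehydrogenase ADH1 went from 2280 ± 54 to 543 ± 31 CPM (-2.07 ± 0.14), GLB1 changed by -2.12 ± 0.13 and the plant cysteine oxidase PCO1 by -1.48 ± 0.09, and the list had adjusted p = 1.83e-20, or adjusted p = 0.0890 with an estimated correlation. The sucrose synthases SUS1 (-2.23 ± 0.12) and SUS4 (-2.41 ± 0.16) are members of that list and of sucrose and starch metabolism. In the pentose phosphate and reductant list 7 of 11 genes were lower and 1 higher (8 and 1 adjusted over the list alone), among them RFNR1 (-1.16 ± 0.08) and G6PD2 (-0.83 ± 0.08), with adjusted p = 2.51e-06, or adjusted p = 0.195 with an estimated correlation. PPC3 fell by 1.24 ± 0.08 and 12 of 23 organic acid genes were lower with 1 higher (13 and 1 adjusted over the list alone; adjusted p = 1.6e-05, adjusted p = 0.219 with an estimated correlation).

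Other groups moved in double mutant roots too. Jasmonate genes rose in 9 of 13 cases (10 adjusted over the list alone), with the repressor JAZ1 at 1.73 ± 0.29 and adjusted p = 6.18e-05, or adjusted p = 0.234 with an estimated correlation. Of 9 anthocyanin genes 6 rose (7 adjusted over the list alone), with the chalcone synthase CHS at 2.91 ± 0.64 and adjusted p = 0.00118, or adjusted p = 0.234 with an estimated correlation. Glucosinolate genes rose in 9 of 11 cases (9 higher and 1 lower adjusted over the list alone), CYP79B2 by 1.23 ± 0.07, with adjusted p = 2.51e-06, or adjusted p = 0.234 with an estimated correlation. Phosphate genes fell in 10 of 17 cases with 1 higher (10 and 1 adjusted over the list alone), PHO1;H1 by -2.81 ± 0.14, with adjusted p = 4.02e-05, or adjusted p = 0.0890 with an estimated correlation. The iron uptake genes IRT1 (-1.55 ± 0.31), NAS1 (-2.09 ± 0.42) and S8H (-2.69 ± 0.33) fell while the regulator BHLH101 rose (1.88 ± 0.33). The cytokinin synthesis genes IPT5 (-1.26 ± 0.13) and CYP735A1 (-1.05 ± 0.13) fell and the cytokinin oxidase CKX5 rose (0.93 ± 0.11). The phosphatase AHG1 (-4.43 ± 0.26), the lipid transfer protein AZI1 (-4.27 ± 0.33) and HMA2 (-4.06 ± 0.28) fell most among the genes named.

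In double mutant roots 5154 genes were called, 2648 higher and 2506 lower, and 1003 changed at least 2-fold. Leaving out any 1 library of the comparison gave 4094 to 4696. The double mutant differed from nlp7-1 in 1334 genes, 499 higher and 835 lower, including UMAMIT36 (-3.73 ± 0.26), the aquaporin NIP2;1 (-2.98 ± 0.26) and the actin-related gene ARP9 (1.71 ± 0.13); the number was 833 without nlp7-1 replicate 1 and 824 without nlp7-1 replicate 2. It differed from nlp2-3 in 1326 genes, 577 higher and 749 lower, including NRT2.5 (3.47 ± 0.17) and PHO1;H1 (-2.17 ± 0.13). That number was 870 without nlp2-3 replicate 3 and 694 when only the groups compared were fitted. Against nlp2-3 the hypoxia list had a median of -1.37 and against nlp7-1 of -1.53, with 11 of 11 members lower in both.

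The interaction asks where the double mutant departs from the sum of both single effects on the log2 scale. In roots 49 genes were called, 13 higher and 36 lower than that sum, out of 1723 with an unadjusted p under 0.05. CYP76G1, a cytochrome P450, lay below the sum (-1.56 ± 0.22) and ARP9 above it (1.27 ± 0.18), each with no call lost in any setting tried. The number fell to 23 without nlp2-3 replicate 3, 27 without nlp7-1 replicate 1, 28 without nlp7-1 replicate 2 and 28 without nlp7-1 replicate 3. DESeq2 called 149 genes, and a replicate block gave 77. Of 25 splits of the libraries 4, the real one included, called at least as many genes, with 1423 in the highest. These splits moved libraries between genotypes and can hold genotype effects, so they neither exclude chance nor speak for it.

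Comparisons against Col-0 overlapped in roots as well. Between nlp2-3 and nlp7-1, 758 genes were called in the same direction, 396 higher and 362 lower, where independent lists would share 30.9 and 24.6. The covariance of fold changes across genes was 0.0941 against 0.0250 in simulated data with the same shared control (r = 0.632 against 0.510). Of the nlp7-1 genes 1433 moved the same way in the double mutant, 779 higher and 654 lower against 119 and 86.4, with a covariance of 0.176 against 0.0250 and r = 0.735 against 0.512. Of the nlp2-3 genes 1291 did, 622 higher and 669 lower against 88.9 and 87.2, with a covariance of 0.159 against 0.0249 and r = 0.738 against 0.512. Opposite directions were called for 12 genes in nlp2-3 with nlp7-1, 7 in nlp7-1 with the double mutant and 5 in nlp2-3 with the double mutant. Simulated data gave no overlapping call in 10 simulations of these root pairs. They held no changed gene, so this number does not show how far real changes would overlap. Part of the excess may still come from the shared Col-0 libraries, since 3 of them cannot be split between comparisons.

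**Figure D2:**
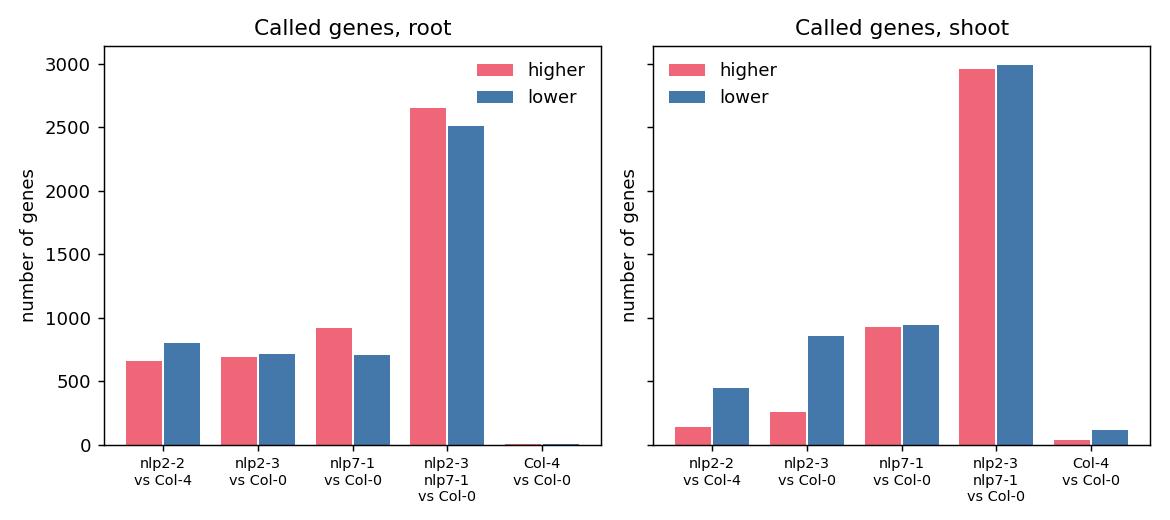
Number of genes called higher (red) and lower (blue) at a BH adjusted p under 0.05 in roots and in shoots, for the 4 mutants and for Col-4 against Col-0. The double mutant has 5154 called genes in roots and 5948 in shoots, against 8 and 152 between the wild types.

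Ammonium carriers rose in 3, 3, 2 and 4 of 4 cases in nlp2-2, nlp2-3, nlp7-1 and the double mutant (4, 3, 4 and 4 adjusted over the list alone), with list p between 1.69e-05 and 0.00404 and adjusted p = 0.0875 at best with an estimated correlation. AMT1;3 lost its call in nlp2-2 without Col-4 replicate 3 or nlp2-2 replicate 1 (adjusted p up to 0.0536), and in the double mutant without the 2 farthest libraries (0.128). AMT2;1 lost it in nlp2-3 without Col-0 replicate 1 or 2 or nlp2-3 replicate 1 or 3 (up to 0.0908), in nlp7-1 without Col-0 replicate 2 (0.0511) and in the double mutant without Col-0 replicate 1 or 2 or double mutant replicate 1 (up to 0.103). In all 3 AMT2;1 also lost it without the 2 farthest libraries (up to 0.224) and with only the groups compared (up to 0.149). Reductant genes fell in 4, 4 and 6 of 11 cases in the single mutants (7, 6 and 8 adjusted over the list alone, with 1, 0 and 1 higher), with list p of 0.000187, 2.61e-05 and 2.88e-06 and adjusted p = 0.247, 0.239 and 0.219 with an estimated correlation. Endodermis and suberin genes rose in 3, 3, 4 and 8 of 10 cases (4, 8, 7 and 10 adjusted over the list alone), with adjusted p = 0.000187, 9.22e-06, 0.000106 and 5.8e-05 and adjusted p = 0.234 at best with an estimated correlation. Low energy genes fell in 4, 3, 5 and 7 of 14 cases with medians of -0.42, -0.43, -0.16 and -0.79 and adjusted p = 4.21e-05, 5.62e-05, 0.00238 and 5.99e-06, and adjusted p = 0.219 at best with an estimated correlation. Root hair genes had medians of 0.54, 0.41, 0.54 and 0.46 with 1, 0, 0 and 2 of 7 called higher (3 each adjusted over the list alone) and list p of 0.00248, 0.00183, 0.00162 and 0.0399, none past 0.05 with an estimated correlation (adjusted p = 0.309, 0.274, 0.288 and 0.418). The double mutant call ended without Col-0 replicate 2 (0.112), double mutant replicate 1 (0.0741) or double mutant replicate 2 (0.0860).

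Iron deficiency genes had medians of -0.39, -0.59, -0.09 and -0.53 in the same order, with list p of 0.00384, 0.00457, 0.0964 and 0.0413. The nlp2-3 call ended without Col-0 replicate 1 (0.0831) and the double mutant call without Col-0 replicate 1 (0.118), Col-0 replicate 3 (0.0537) or double mutant replicate 2 (0.0858). Nitrate signalling passed its test in nlp2-2 (7 lower, adjusted p = 0.0196) unless Col-4 replicate 2 (0.166) or nlp2-2 replicate 3 (0.209) was left out, and in nlp2-3 (7 lower and 1 higher, adjusted p = 0.0437) unless Col-0 replicate 1 (0.424) or nlp2-3 replicate 2 (0.443) was left out. The nitrate transport list, with members in both directions, had 9, 8, 8 and 10 of 23 lower and 2, 4, 4 and 9 higher. Its test passed in nlp7-1 alone (adjusted p = 0.0301), but not without Col-0 replicate 1 (0.0730) or nlp7-1 replicate 1 (0.0702), and its median in nlp2-2 was 0.05 with a mean of -0.19. Organic acid genes fell in 2, 3 and 3 of 23 cases in the single mutants (adjusted p = 0.00125, 0.000255 and 0.0109, the last 0.0740 without Col-0 replicate 1). Sucrose and starch genes passed in nlp2-2 (adjusted p = 0.00928) and in nlp7-1 (adjusted p = 0.0301, or 0.0606 without Col-0 replicate 1). Anthocyanin genes passed in nlp2-3 (adjusted p = 0.0376), but not without Col-0 replicate 1 (0.267), Col-0 replicate 2 (0.0509) or nlp2-3 replicate 2 (0.0985), and jasmonate genes in nlp7-1 had a median of 0.67 (adjusted p = 0.000106) with 0 of 13 called, 8 with an unadjusted p under 0.05 and 5 called by DESeq2. None of the calls in this paragraph held with an estimated correlation, where adjusted p = 0.150 was the smallest.

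Senescence passed in nlp7-1 alone (2 of 8 higher, adjusted p = 0.0301, or 0.0576 without Col-0 replicate 2; adjusted p = 0.221 with an estimated correlation). Nitrogen assimilation in the single mutants had 3 to 5 of 17 members higher and 4 to 6 lower and did not pass (adjusted p = 0.928, 0.628 and 0.259). Cytokinin, sulfur deficiency, salicylate defence, flowering, circadian clock, heat shock, photosynthesis, abscisic acid with cold and drought, xylem and cell cycle passed in no root comparison. Several of these lists still held called genes in the double mutant, with 7 lower and 2 higher of 19 cytokinin genes (adjusted p = 0.104), 5 higher and 1 lower of 12 for abscisic acid with cold and drought (median 0.43, adjusted p = 0.0668) and 3 higher and 2 lower of 6 for heat shock (adjusted p = 0.555), the same numbers adjusted over the list alone. No xylem or cell cycle gene was called by edgeR in any mutant root, with 0 to 2 members of a list under an unadjusted p of 0.05 and at most 1 called by DESeq2.

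Shoots of nlp2-2 were compared with Col-4 to ask whether the leaf responds as the root does. The clearest group was salicylate defence, the genes induced when leaves meet biotrophic pathogens: 12 of 16 fell and none rose (15 adjusted over the list alone), with the marker PR1 at -4.05 ± 0.54 (from 51.6 ± 11 to 3.14 ± 1.9 CPM), the pipecolate synthesis gene ALD1 at -3.66 ± 0.53 and the lipase-like regulator PAD4 at -0.72 ± 0.11. That list had a median of -0.74 and kept its call with an estimated correlation (adjusted p = 8.78e-25, adjusted p = 0.0242 with an estimated correlation). NPF6.3/NRT1.1 (-0.05, adjusted p = 0.86), NIA1 (0.05, adjusted p = 0.95), NIR1 (-0.36, adjusted p = 0.25) and NRT2.1 (-0.77, adjusted p = 0.67) were not called. NRT3.1 (-1.25 ± 0.14), the glutamate synthase GLT1 (-0.39 ± 0.07) and DUR3 (-0.67 ± 0.14), which rose in roots, fell. NIA2 was called higher (0.31 ± 0.07) unless Col-4 replicate 1 or 3, nlp2-2 replicate 3 or the 2 farthest libraries were left out (adjusted p up to 0.335). NF-YA2 (1.53 ± 0.12), NF-YA10 (1.38 ± 0.11), the transcription factor gene MEE3 (0.93 ± 0.10) and the sucrose carrier SWEET13 (1.01 ± 0.10) rose.

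Reductant genes also fell in nlp2-2 shoots, in 5 of 11 cases (5 adjusted over the list alone), G6PD3 at -0.90 ± 0.14, and the list kept its call (adjusted p = 5.33e-05, adjusted p = 0.0460 with an estimated correlation). Glucosinolate genes fell in 7 of 14 cases (11 adjusted over the list alone), CYP79F1 at -0.29 ± 0.06, and kept theirs (adjusted p = 8.99e-12, adjusted p = 0.0242 with an estimated correlation). In all 586 genes were called, 141 higher and 445 lower, 183 at least 2-fold. The number was 338 without Col-4 replicate 3 and 345 without nlp2-2 replicate 1, and 226 without the libraries nlp2-2 replicates 2 and 3 that lay farthest from their group mean, a setting chosen after seeing the data that leaves 1 nlp2-2 library. Against Col-0 the count was 1360 (887 lower), or 2108 with a replicate block. It was 882 when only the groups compared were fitted, 587 without Col-0 replicate 3 and 779 without nlp2-2 replicate 2. Against Col-0 PR1 was at -4.15 ± 0.54, NF-YA2 at 1.34 ± 0.12 and NLP2 at -0.90 ± 0.07. Both wild types gave the same direction for 435 genes and opposite directions for none, again with the same nlp2-2 libraries in both comparisons.

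In nlp2-3 shoots against Col-0 the same defence genes fell. All 16 salicylate defence genes were lower, also adjusted over the list alone, with PR1 at -5.73 ± 0.63, PR2 at -3.47 ± 0.29, PR5 at -2.30 ± 0.19 and the regulators EDS1 (-1.14 ± 0.11) and PAD4 (-1.12 ± 0.11), a median of -2.10 and adjusted p = 8.75e-34 (adjusted p = 0.00804 with an estimated correlation). NPF6.3/NRT1.1 (-0.09, adjusted p = 0.62), NIA1 (0.00, adjusted p = 1.00), NIR1 (-0.29, adjusted p = 0.33) and NRT2.1 (0.95, adjusted p = 0.54) were not called, and NIA2 rose (0.35 ± 0.07). NRT3.1 (-1.83 ± 0.14), DUR3 (-1.58 ± 0.15), the phloem nitrate carrier NPF2.13/NRT1.7 (-0.66 ± 0.12), GLN1;1 (-0.74 ± 0.10), GLT1 (-0.33 ± 0.07) and the regulators TGA1 (-0.57 ± 0.11) and LBD37 (-0.48 ± 0.08) fell. NF-YA2 (1.42 ± 0.12), NF-YA10 (1.34 ± 0.11), MEE3 (1.05 ± 0.10) and SWEET11 (0.62 ± 0.10) rose. Anthocyanin genes rose in 7 of 13 cases (11 adjusted over the list alone), with the acyltransferase 5MAT at 1.07 ± 0.16 and adjusted p = 4.92e-12, or adjusted p = 0.0708 with an estimated correlation. A chitinase listed as CHI (AT2G43570) fell by 3.60 ± 0.36 on the log2 scale, and it is not the chalcone isomerase CHI (AT3G55120) of the anthocyanin list.

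In nlp2-3 shoots 1110 genes were called, 254 higher and 856 lower, 402 at least 2-fold, and leaving out 1 library gave 755 to 1065. Of these, 403 were called in the same direction in nlp2-2 shoots, 54 higher and 349 lower, where independent lists would share 1.87 and 19.9. Opposite directions were called for 3 genes. The covariance of fold changes was 0.0936 against a simulated 0.000113 (r = 0.513 across genes), again with no shared library.

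In shoots of nlp7-1 several nitrogen genes rose. NPF6.3/NRT1.1 (0.47 ± 0.07) and NPF7.3/NRT1.5 (0.87 ± 0.13), both lower in roots, rose. So did NIA2 (0.61 ± 0.07), the ferredoxin-dependent glutamate synthase GLU1 (0.29 ± 0.05) and the anion channel SLAH3 (0.54 ± 0.10). NIR1 rose (0.68 ± 0.14), a call that ended without Col-0 replicate 3 (adjusted p = 0.0508), and NIA1 (-0.15, adjusted p = 0.74) and NRT2.1 (1.42, adjusted p = 0.16) were not called. Reductant genes, lower in nlp2-2 shoots, were higher in 5 of 11 cases (7 adjusted over the list alone), PGD3 by 0.59 ± 0.09 (adjusted p = 3.18e-05, adjusted p = 0.0610 with an estimated correlation). BT1 (-0.63 ± 0.11), NPF1.2/NRT1.11 (-0.39 ± 0.07) and DUR3 (-0.90 ± 0.14) fell. ESC, a nuclear protein of the AT-hook family, rose most: from 0.350 ± 0.212 CPM in Col-0 to 13.4 ± 2.0 in nlp7-1 (5.30 ± 0.29), while in nlp7-1 roots it fell by 1.68 ± 0.11 on the log2 scale. The tryptophan glucosinolate gene CYP79B2 (1.23 ± 0.10), the flowering regulator SPL4 (1.51 ± 0.16) and the light-stress protein ELIP1 (1.3 ± 0.14) rose.

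Salicylate defence genes fell in nlp7-1 shoots in 10 of 16 cases (14 adjusted over the list alone), PR1 at -3.01 ± 0.47 and PBS3 at -1.03 ± 0.12, with a median of -0.97 and adjusted p = 1.92e-14 (adjusted p = 0.0610 with an estimated correlation). Genes of abscisic acid, cold and drought fell in 8 of 14 cases (10 adjusted over the list alone), COR15A at -1.26 ± 0.13 and RAB18 at -0.67 ± 0.11, with a median of -0.62 and adjusted p = 9.78e-10 (adjusted p = 0.0515 with an estimated correlation). Sulfur deficiency genes passed with a median of 0.31 and 4 of 9 higher (7 adjusted over the list alone; adjusted p = 2.3e-05, adjusted p = 0.184 with an estimated correlation). QQS fell by 4.05 ± 0.24 on the log2 scale, and Col-4 over Col-0 shoots was -3.43 ± 0.23. In all 1870 genes were called, 926 higher and 944 lower, 258 at least 2-fold. That number was 955 without Col-0 replicate 3, 1144 without nlp7-1 replicate 1 and 1231 without nlp7-1 replicate 2.

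In shoots of the double mutant 8 of 18 nitrate transport genes were higher and 4 lower (9 and 4 adjusted over the list alone). NPF7.3/NRT1.5 (1.60 ± 0.13), SLAH3 (1.3 ± 0.10), the vacuolar nitrate carrier CLCA (1.00 ± 0.11), NPF6.3/NRT1.1 (0.44 ± 0.07), NIA2 (0.38 ± 0.07) and NRT2.1 (2.28 ± 0.59, at 1.58 ± 0.94 CPM) rose. NIA1 (-1.32 ± 0.22), DUR3 (-1.41 ± 0.14), the asparagine synthetase ASN2 (-1.18 ± 0.08), NPF1.2/NRT1.11 (-0.86 ± 0.07), LBD38 (-1.02 ± 0.10) and LBD37 (-0.76 ± 0.08) fell, and NIR1 was not called (-0.36, adjusted p = 0.071). The sucrose exporters SWEET11 (1.51 ± 0.10) and SWEET12 (2.63 ± 0.26) rose and the fumarase FUM2, which makes the fumarate leaves store, fell (-1.18 ± 0.14). All 13 anthocyanin genes rose, also adjusted over the list alone, 5MAT by 2.2 ± 0.15 and the regulator TT8 by 2.00 ± 0.18, with a median of 1.78 and adjusted p = 1.22e-13 (adjusted p = 0.0679 with an estimated correlation). ESC rose by 5.42 ± 0.28 and CYP79B2 by 1.61 ± 0.10. DIN2, a dark-induced glucosidase, was at 0 counts in every Col-0 shoot library and at 1.24 ± 0.71 CPM here, at least 29.4-fold higher than 3 counts over the Col-0 group allow, counting error only.

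Salicylate defence genes fell in 15 of 16 cases in double mutant shoots (15 adjusted over the list alone), PR1 at -3.63 ± 0.50, with a median of -1.75 and adjusted p = 3.34e-13 (adjusted p = 0.0679 with an estimated correlation). Abscisic acid, cold and drought genes fell in 10 of 14 cases (10 adjusted over the list alone), COR15A at -1.65 ± 0.13, with adjusted p = 1.86e-06 (adjusted p = 0.0679 with an estimated correlation). Photosynthesis genes fell by small amounts in 13 of 19 cases with 1 higher, also adjusted over the list alone, LHCA1 at -0.44 ± 0.06, with a median of -0.23 and adjusted p = 6.92e-05 (adjusted p = 0.472 with an estimated correlation). Xylem genes fell in 5 of 6 cases (6 adjusted over the list alone), XCP1 at -0.77 ± 0.11, with adjusted p = 0.00334 (adjusted p = 0.307 with an estimated correlation). Nitrate signalling had 10 of 24 lower and 3 higher (12 and 3 adjusted over the list alone; adjusted p = 0.0196, adjusted p = 0.0679 with an estimated correlation). Cytokinin synthesis gene IPT3 fell by 1.36 ± 0.15 on the log2 scale. In all 5948 genes were called, 2958 higher and 2990 lower, 933 at least 2-fold, and leaving out 1 library gave 4794 to 5123.

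The double mutant differed from nlp7-1 shoots in 1530 genes, 721 higher and 809 lower, among them the glucosidase BGLU11 (1.5 ± 0.14), TT8 (1.48 ± 0.18), DFR (1.38 ± 0.25) and NLP2 itself (-2.56 ± 0.07); that number was 921 without nlp7-1 replicate 1 and 965 without double mutant replicate 2. It differed from nlp2-3 in 5081 genes, 2607 higher and 2474 lower, among them ESC (5.20 ± 0.28), the nitrilase NIT2 (3.64 ± 0.43) and the haem oxygenase HO3 (-2.04 ± 0.15). The interaction of both mutations was called in 719 shoot genes, 405 above and 314 below the sum of both single effects, or 1233 genes with a replicate block. NLP2 lay below it (-0.82 ± 0.10), and SAG13 (3.91 ± 0.53), PR1 (5.11 ± 0.89) and QQS (3.02 ± 0.38) above it. PR1 stood at 1.08 to 6.68 CPM on average in nlp2-3, nlp7-1 and the double mutant, against 55.4 ± 19 CPM in Col-0. QQS was at 28.3 ± 1.7 CPM in Col-0 shoots and at 1.49 to 3.09 in the other groups, Col-4 included, so its value comes from the Col-0 libraries.

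Overlaps in shoots against Col-0 were as follows. Between nlp2-3 and nlp7-1, 460 genes were called in the same direction, 71 higher and 389 lower, where independent lists would share 12.3 and 42.2, with a covariance of 0.102 against a simulated 0.0254 (r = 0.543 against 0.502). Between nlp7-1 and the double mutant 1684 were, 814 and 870 against 143 and 147, with a covariance of 0.174 against 0.0251 (r = 0.775 against 0.500). Between nlp2-3 and the double mutant 793 were, 125 and 668 against 39.3 and 134, with a covariance of 0.157 against 0.0255 (r = 0.580 against 0.497). Opposite directions were called for 31 genes in nlp2-3 with nlp7-1, 11 in nlp7-1 with the double mutant and 38 in nlp2-3 with the double mutant. Simulated data gave 0 to 0.1 shared calls on average over 10 simulations. They held no changed gene, so this number does not show how far real changes would overlap. Part of the excess may come from the shared Col-0 libraries.

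**Figure D3:**
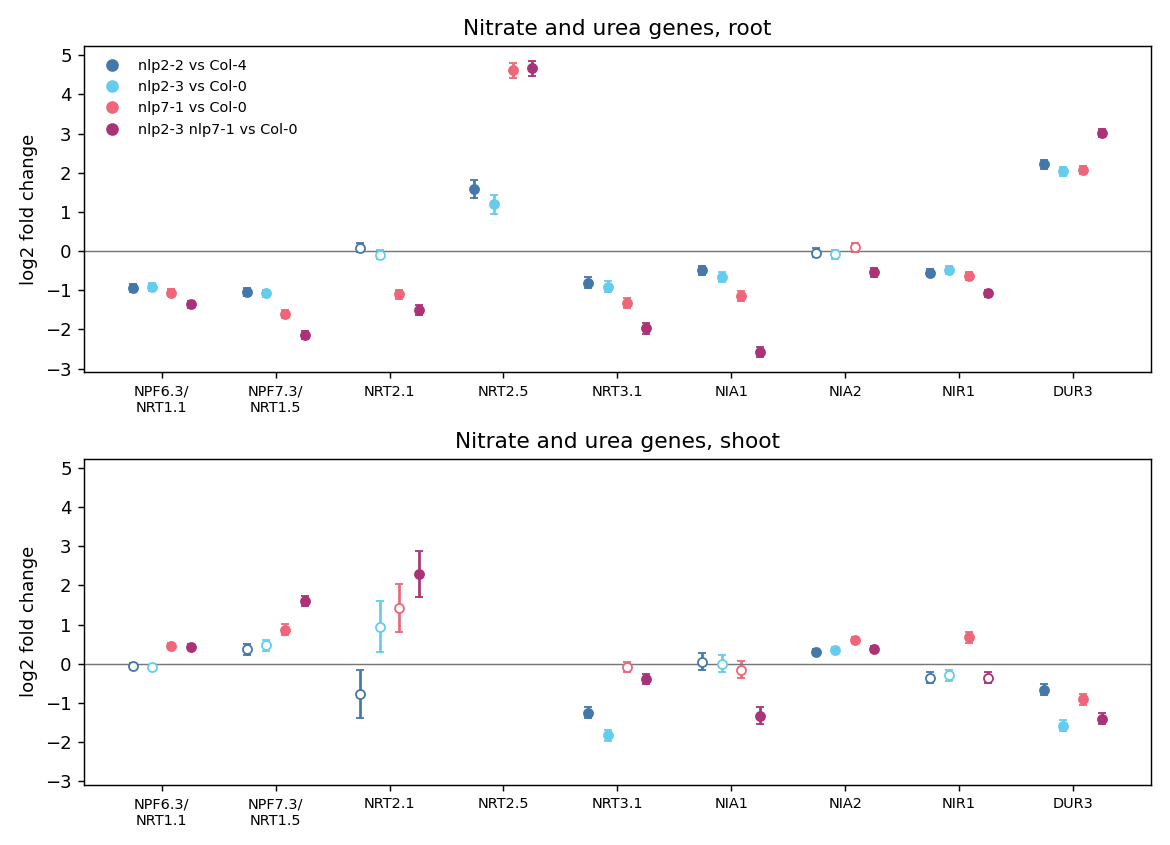
Log2 fold change with its standard error of 9 nitrate and urea genes in roots (top) and shoots (bottom) for each mutant against its wild type, n = 3 per group; filled points were called and open points were not. DUR3 rises in every mutant root (2.03 to 3.01) and falls in every mutant shoot (-0.67 to -1.58), and NRT2.5 was not measured in shoots.

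**Figure D4:**
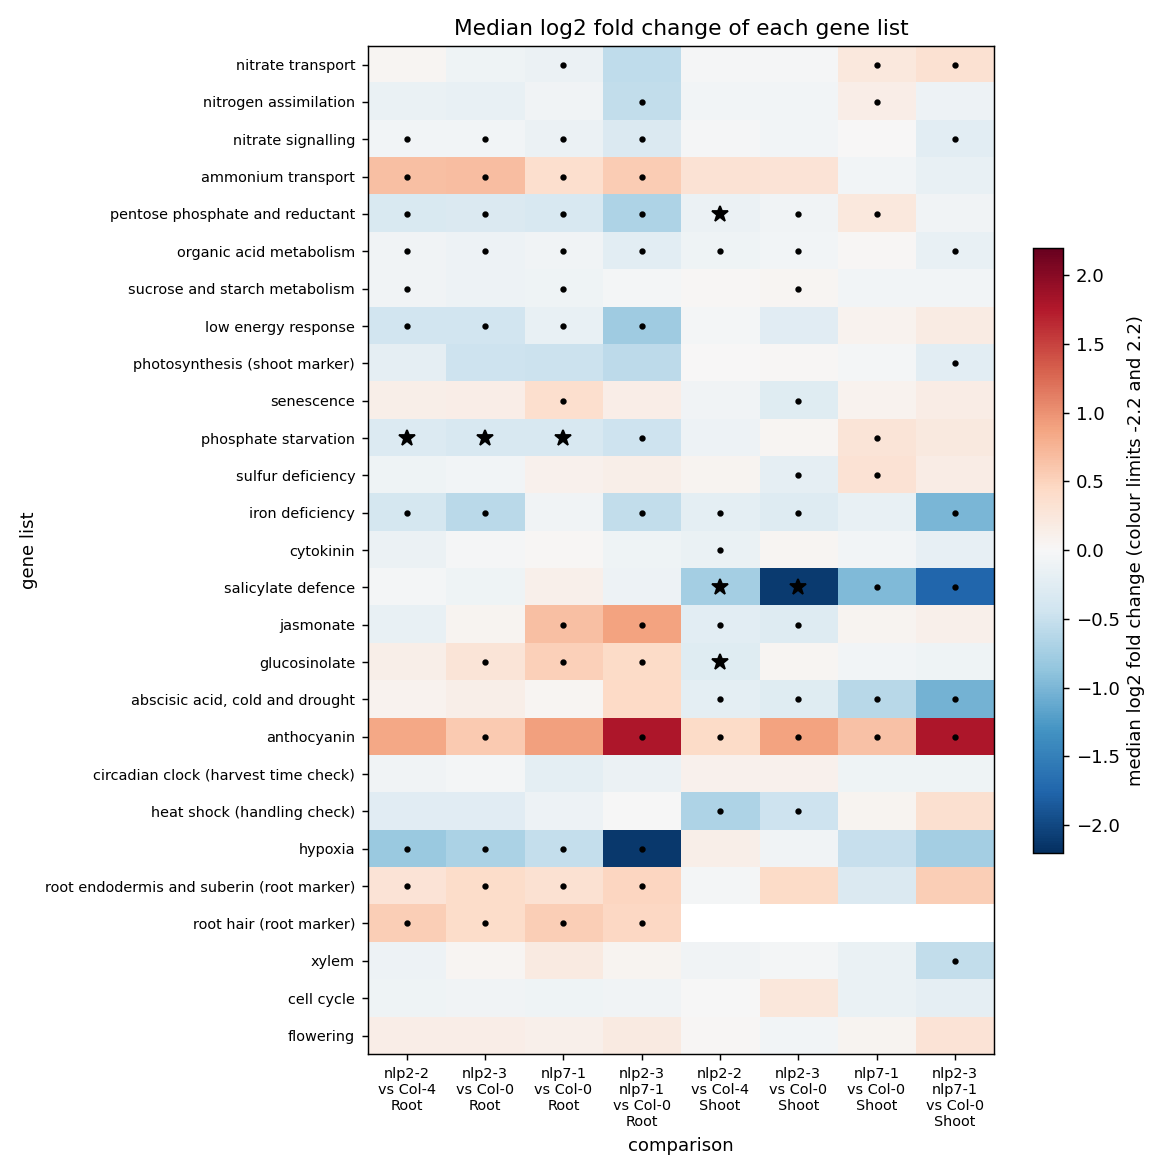
Median log2 fold change (colour) of 27 gene lists in the 8 comparisons of a mutant with its wild type; dots mark lists past the camera test with the preset correlation and stars those also past it with an estimated one. Hypoxia is lowest in double mutant roots (-2.12) and salicylate defence in nlp2-3 shoots (-2.10); root hair genes were not measured in shoots.

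Further lists passed in shoots. Organic acid genes fell in 2, 5 and 10 of 22 cases in nlp2-2, nlp2-3 and the double mutant (4, 8 and 11 adjusted over the list alone; adjusted p = 0.000769, 0.000247 and 0.0250, and adjusted p = 0.0510, 0.0556 and 0.234 with an estimated correlation). Anthocyanin genes passed in nlp2-2 (0 of 13 called, 7 with an unadjusted p under 0.05 and none by DESeq2; adjusted p = 2.15e-06, adjusted p = 0.166 with an estimated correlation) and in nlp7-1 (3 higher, 8 adjusted over the list alone; adjusted p = 2.17e-06, adjusted p = 0.184 with an estimated correlation). Nitrogen assimilation passed in nlp7-1 alone (5 of 17 higher and 1 lower, 8 and 2 adjusted over the list alone; adjusted p = 0.0125, adjusted p = 0.184 with an estimated correlation), and in the double mutant it had 5 higher and 6 lower (adjusted p = 0.418). Phosphate starvation genes, lower in roots, passed upward in nlp7-1 (3 of 14 higher, 4 adjusted over the list alone; adjusted p = 0.00295, adjusted p = 0.184 with an estimated correlation), with MGD3 at 1.24 ± 0.22. Abscisic acid, cold and drought genes passed in nlp2-3 (2 of 14 lower, adjusted p = 0.00433) and in nlp2-2 (adjusted p = 0.00673, or 0.366 without nlp2-2 replicate 1), with adjusted p = 0.271 at best with an estimated correlation. Glucosinolate genes went both ways in nlp7-1 (4 higher and 2 lower of 14) and in the double mutant (5 and 5), CYP79F1 at -0.42 ± 0.06 and -0.47 ± 0.06, and did not pass, with a median of -0.05 and a mean of 0.12 in nlp7-1.

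Some shoot list calls rested on single libraries. In nlp2-2 iron deficiency (adjusted p = 0.00673) ended without nlp2-2 replicate 2 (0.179) and jasmonate (adjusted p = 0.000860) without nlp2-2 replicate 1 (0.175). Cytokinin (adjusted p = 0.0281) ended without Col-4 replicate 1 (0.167) or 3 (0.107) or nlp2-2 replicate 2 (0.0669) or 3 (0.0894), and heat shock (adjusted p = 0.00992) without Col-4 replicate 1 (0.0621) or nlp2-2 replicate 2 (0.0696). In nlp2-3 the lists pentose phosphate, sucrose and starch, senescence, sulfur deficiency, iron deficiency, jasmonate and heat shock had adjusted p = 0.0468, 0.0437, 0.0293, 0.0428, 0.0428, 0.0144 and 0.0396. Without Col-0 replicate 1 the pentose phosphate (0.112), sucrose and starch (0.132) and heat shock (0.112) calls ended; without Col-0 replicate 2 those of pentose phosphate (0.134), sulfur (0.0974) and iron (0.0967) did. Without Col-0 replicate 3 the sulfur (0.220), iron (0.110), jasmonate (0.0706) and heat shock (0.0852) calls ended, and without nlp2-3 replicate 1 those of pentose phosphate (0.225), sulfur (0.621) and iron (0.114). Without nlp2-3 replicate 2 sucrose and starch (0.149), senescence (0.0637), iron (0.196), jasmonate (0.0603) and heat shock (0.0603) ended, and without nlp2-3 replicate 3 pentose phosphate (0.0707), sucrose and starch (0.137), jasmonate (0.122) and heat shock (0.0707). Nitrate transport passed in nlp7-1 (median 0.24, adjusted p = 0.0276) unless Col-0 replicate 1 (0.0983), Col-0 replicate 2 (0.0689), nlp7-1 replicate 1 (0.0682) or nlp7-1 replicate 3 (0.0572) was left out. In the double mutant it passed (median 0.33, adjusted p = 0.0492) unless Col-0 replicate 1 (0.0899) or Col-0 replicate 2 (0.0672) was. None of these calls held with an estimated correlation, where adjusted p = 0.115 was the smallest.

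Iron deficiency genes in the double mutant had a median of -1.0 with 4 of 15 lower (adjusted p = 0.0234, adjusted p = 0.580 with an estimated correlation), NAS4 at -1.85 ± 0.24. Hypoxia, low energy response, ammonium transport, circadian clock, flowering, cell cycle and endodermis and suberin passed in no shoot comparison, and the root hair genes were not measured there. The hypoxia list, lower in roots, had shoot medians of 0.12, -0.07, -0.51 and -0.75 in nlp2-2, nlp2-3, nlp7-1 and the double mutant, with 4 of 10 members lower and 1 higher in the last. The low energy list had a median of 0.18 and a mean of 0.73 in the double mutant, where DIN2 lies above the median whether at its fitted value or its bound.

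Col-4 and Col-0 were compared to see how far the wild types differ. In roots 8 genes were called, 3 higher and 5 lower in Col-4, out of 948 with an unadjusted p under 0.05. AT3G05170 (4.00 ± 0.25), AT3G05945 (2.58 ± 0.13) and AT2G06995 (6.27 ± 0.81) were higher. AT3G05955 (-4.08 ± 0.56), AT5G08250 (-1.59 ± 0.21), AT5G24240 (-3.75 ± 0.28) and QQS (-5.32 ± 0.39) were lower, and so was AT3G18535, which had 0 counts in Col-4 roots and 24.0 ± 1.3 CPM in Col-0, at least 518-fold less than 3 counts over the group allow. The number rose to 18 without Col-0 replicate 1, 18 with a replicate block and 20 by DESeq2. In shoots 152 genes were called, 35 higher and 117 lower, among them QQS (-3.43 ± 0.23), ASG4 (-1.01 ± 0.16), BBX29 (-0.99 ± 0.16) and NLP2 (-0.37 ± 0.07). That number was 70 without Col-0 replicate 2, 50 without Col-0 replicate 3, 57 without Col-4 replicate 1, 58 without Col-4 replicate 2, 622 with a replicate block and 332 by DESeq2. At some of these genes mutants differ from their own control: AT3G18535 stood at 23.2 ± 1.1 CPM in nlp2-2 roots, and AT3G05170 at 0.609 ± 0.434 in Col-0 roots but 9.56 to 10.7 in the mutants. Whether each mutant shares a parental line with its control is therefore not settled, and called genes can include differences between lines.

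The effect of each mutation was also compared between shoots and roots in the fit of all libraries. It differed in 569 genes for nlp2-2, 912 for nlp2-3, 1378 for nlp7-1 and 5008 for the double mutant. NPF6.3/NRT1.1 was among them in all 4, with differences of 0.88, 0.80, 1.52 and 1.8, shoot minus root. NPF7.3/NRT1.5 differed by 2.47 in nlp7-1 and 3.74 in the double mutant, and NRT2.1 by 2.54 and 3.78. ESC differed by 6.98 in nlp7-1 and 6.5 in the double mutant. The nlp2-2 number was 899 by DESeq2 and 1046 by limma on log2(FPKM + 1). For nlp2-3, 2 of 25 splits of the libraries, the real one included, called as many genes. Other splits can hold genotype effects, so they neither exclude chance there nor speak for it. The nlp7-1 number was 802 without Col-0 root replicate 2 and 832 without Col-0 shoot replicate 3, and 850 without the 2 libraries of each tissue farthest from their group means.

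**Figure D5:**
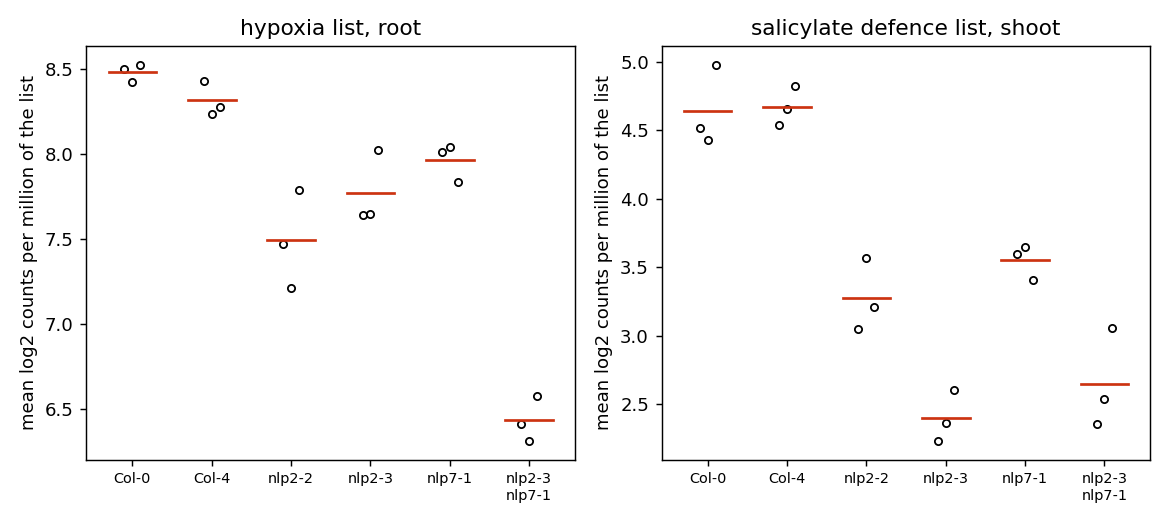
Mean log2 CPM of the hypoxia list in root libraries (left) and of the salicylate defence list in shoot libraries (right), with each library as an open circle and the mean of each genotype as a red line. Hypoxia scores lie at 8.23 to 8.52 in the wild types and 6.31 to 6.58 in the double mutant, and salicylate scores at 4.43 to 4.98 and 2.35 to 3.06.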

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

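The test of a rise of ESC in every tissue was chosen only after the result was seen. The values here are differences in the effect of a mutation, shoot minus root, on the log2 scale, each past an edgeR quasi-likelihood test of that difference with BH adjustment. No group held 4 samples or more, so no single library was tested as an outlier, and the deposited files held no data outside the comparisons.

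For nlp2-2 against Col-4 the effect differed in 569 genes. Among those named the differences were NPF6.3/NRT1.1 0.88, NLP2 1.08, GLN1;4 -0.88, FMO1 -4.20, UGT76B1 -4.86, LAS1 -3.79, MBP1 4.18, GPT2 4.37 and ARGAH2 6.09. For nlp2-3 it differed in 912 genes: NPF6.3/NRT1.1 0.80, NRT3.1 -0.93, GLN1;1 -1.24 (0.48 in roots and -0.74 in shoots), NLP2 -0.92, FMO1 -5.09, UGT76B1 -8.18, LAS1 -4.39, UMAMIT36 3.02, COPT6 4.95, SWEET11 2.54 and ACA1 5.75.

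For nlp7-1 the effect differed in 1378 genes. Nitrogen genes among them were NPF6.3/NRT1.1 1.52, NPF7.3/NRT1.5 2.47, NRT2.1 2.54, NRT2.5 -5.34, NIA1 0.98, NIA2 0.50, NIR1 1.3, NAC4 2.72, BT1 1.06 and NLP2 -0.53. The others were RFNR2 1.04, G6PD2 1.01, SUS1 0.94, WOX11 3.52, ESC 6.98, scpl3 -5.70 and ABCA8 -4.80.

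For the double mutant it differed in 5008 genes. Nitrogen and carbon genes were NPF6.3/NRT1.1 1.8, NPF7.3/NRT1.5 3.74, NRT2.1 3.78, NIA1 1.25, NIA2 0.91, NIR1 0.72, RFNR1 0.32, RFNR2 0.60, SUS1 2.48, TPS9 1.92 and NLP2 -2.16. The others were ESC 6.5, ADH1 1.45, FMO1 -5.50, PHO1;H1 1.79, SQD1 0.45, CYP79B2 0.38, CHI (AT3G55120) -1.02, MBP2 6.41, UMAMIT14 6.33, MAKR4 -5.62, RABA1e -6.73 and COR15A -3.93 (2.27 in roots and -1.65 in shoots). The mutant shoot libraries held 0 counts of scpl3, ABCA8, MAKR4 and RABA1e, so their values depend on the prior count. NRT2.5 in nlp7-1 does too, with at most 3 counts in any nlp7-1 shoot library and 4 in any Col-0 one, below the filter for shoots. UGT76B1 had at most 1 count in nlp2-3 shoots, and ARGAH2, COPT6 and ACA1 were below the filter in roots. Some of these calls ended when 1 library was left out, given with the highest adjusted p among them: MBP1 (Col-4 root replicate 2, nlp2-2 root replicate 1 or 2; 0.102), GPT2 (Col-4 root replicate 1 or nlp2-2 root replicate 2; 0.113) and ARGAH2 (nlp2-2 root replicate 2; 0.0510). So did COPT6 (Col-0 root replicate 2 or 3, nlp2-3 root replicate 1 or 3; 0.0750) and ABCA8 (every library of the comparison except Col-0 root replicates 1 and 3, Col-0 shoot replicate 2 and nlp7-1 root replicate 2; 0.196). Calls ended in other settings too: by limma on log2(FPKM + 1) those of ACA1 (0.299), MBP1 (0.886), ARGAH2 (0.271), COPT6 (0.293) and MBP2 (0.428, with its sign reversed). Without the 2 farthest libraries those of MBP1 (0.0825), COPT6 (0.0695), ABCA8 (0.0597) and MBP2 (0.0517) ended, and with only the groups compared those of GPT2 (0.0579) and ABCA8 (0.0706).

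The libraries were split in 25 ways, the real one included. Only the real split called as many genes for nlp2-2 (569, highest other 323), nlp7-1 (1378, highest other 439) and the double mutant (5008, highest other 3446). That puts the share under 0.05. For nlp2-3 it was 2 of 25 (912, highest other 1536), so chance is not excluded there. The splits moved libraries between genotypes within each tissue, so other splits can still hold genotype effects. They therefore test for any effect of genotype and cannot decide whether that effect differs between tissues.

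ESC rose in shoots of nlp7-1 and of the double mutant and fell in roots of both. A chromosomal change spanning the region would raise its neighbours, but 0 of 7 measured genes within 20 kb were called at least 2-fold higher in nlp7-1 shoots by edgeR (1 with an unadjusted p under 0.05, 0 by DESeq2). A rise in every tissue that lacks NLP7 was not seen, as ESC changed by -1.68 ± 0.11 in nlp7-1 roots. Reads shared with other AT-hook genes would raise others too. At least 1 called at least 2-fold higher was set in advance as the outcome under this explanation. Of 18, 1 was, so the preset test went with shared reads. That gene was AHL17, from 0.223 ± 0.105 to 0.947 ± 0.246 CPM against 13.4 ± 2.0 for ESC. Of the 3 family genes called besides ESC, AHL17 included, AHL8 reached the highest level, from 2.95 ± 0.35 to 4.49 ± 0.43 CPM. These levels, a comparison not set in advance, argue against reads from the 3 called genes as the source of the rise. For the genes not called, shared reads stay open. A difference of parental line was not tested and stays open too.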

How the results depend on the processing

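One alternative, leaving out the 2 libraries of each tissue farthest from their group means, was chosen after seeing the data; it leaves 1 nlp2-2 shoot library, assumed to vary like the others. Numbers of called genes moved over 1.5 times as follows. With only the groups compared: nlp2-3 roots 659, nlp2-2 against Col-0 roots 1140 and shoots 882, double mutant against nlp2-3 roots 694. With a replicate block: Col-4 against Col-0 18 in roots and 622 in shoots, interaction 77 and 1233, nlp2-2 against Col-0 shoots 2108; in 8 of 16 pair comparisons each library of the first group correlated best with the same number of the second, a hint from the data only. By DESeq2: Col-4 against Col-0 20 and 332, root interaction 149, nlp2-2 tissue difference 899, which was 1046 by limma on log2(FPKM + 1). Without the 2 libraries: nlp2-2 shoots 226 against Col-4 and 350 against Col-0, tissue differences 337 for nlp2-2 and 850 for nlp7-1. Leaving out 1 library gave in roots 846 to 1395 (nlp2-2), 855 to 1439 (nlp2-3), 1010 to 1773 (nlp7-1), 8 to 18 (Col-4 against Col-0), 987 to 1697 (nlp2-2 against Col-0), 824 to 1074 and 870 to 1197 (double mutant against nlp7-1 and nlp2-3) and 23 to 67 (interaction). In shoots it gave 338 to 540 (nlp2-2), 955 to 1595 (nlp7-1), 50 to 205 (Col-4 against Col-0), 587 to 1308 (nlp2-2 against Col-0), 921 to 1185 (double mutant against nlp7-1), and 802 to 1731 for the nlp7-1 tissue difference. Of 603 results for named genes 472 lost no call in any setting, a number that includes genes that were not called and had none to lose. MBP2 alone reversed, its double mutant tissue difference going from 6.41 to -0.32 by limma on log2(FPKM + 1). Gene list tests passed in 89 cases, 7 with an estimated correlation, 88 with RLE scaling and 95 with a replicate block. Apart from smaller groups in the settings that leave libraries out, the cause was not tested.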

Other observations

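The tests of a high level in Col-0 alone, of a graded loss and of the time of harvest were chosen only after the results were seen. The urea carrier gene DUR3 rose in all 4 mutant roots and fell in all 4 mutant shoots. The nitrate reductase gene NIA2 was called higher in all 4 mutant shoots (0.31, 0.35, 0.61 and 0.38), the first with an adjusted p up to 0.335 when Col-4 replicate 1 or 3, nlp2-2 replicate 3 or the 2 farthest libraries were left out. In double mutant shoots the nitrilase NIT2 (2.56 ± 0.39) and the glucosinolate gene CYP79F2 (1.34 ± 0.14) were higher and PCC1 (-3.33 ± 0.41) and NUDT6 (-3.05 ± 0.27) lower. The abscisic acid synthesis gene NCED3 (-1.66 ± 0.26) and the malic enzyme NADP-ME2 (-0.84 ± 0.09) fell there, and the galactolipid synthase MGD3 rose (1.76 ± 0.22). In nlp2-2 shoots LURP1, a gene for resistance to an oomycete, fell by 2.27 ± 0.30 on the log2 scale, and in nlp2-3 shoots by 3.40 ± 0.32. GPT2, a plastid sugar phosphate carrier, rose in nlp2-3 shoots (1.17 ± 0.23), or adjusted p = 0.0576 with only the groups compared.

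Some genes separate groups in ways that match neither the mutations nor the controls; these were chosen after their values were seen. AT3G18535 had 0 counts in Col-4 roots and stood at 21.5 to 24.6 CPM in every other root group. AT3G05170 was at 0.609 ± 0.434 CPM in Col-0 roots and 9.56 to 10.7 in the others, and AT3G05945 at 2.15 ± 0.013 and 11.4 to 12.8. AT5G24240 was at 88.2 and 84.6 CPM in roots of Col-0 and nlp2-3 and at 6.14 to 9.74 in the other 4 root groups, so nlp7-1 and the double mutant match Col-4 there and not their control Col-0. These values leave in doubt whether mutants and wild types share a parental line.

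Hypoxia genes were lower in mutant roots. A high level in the Col-0 libraries alone is argued against by nlp2-2, whose control was Col-4 and whose list median was -0.81. All 6 of 6 wild-type root libraries lay above every nlp2-2, nlp2-3 and double mutant library, at 8.23 to 8.52 against 6.31 to 8.02, with nlp7-1 at 7.83 to 8.04. This separation had been set in advance to rule out a difference between pots independent of genotype, wrongly, since the sample labels give no pots and pots that each held 1 genotype would separate the libraries alike. That difference stays open. The median of -1.37 in the double mutant against nlp2-3 follows from the medians against Col-0, so it tests no graded loss with each NLP gene removed. Oxygen, nitric oxide and tissue density were not measured, and neither these nor a difference of parental line was tested.

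Salicylate defence genes were lower in mutant shoots. A high level in the Col-0 libraries alone is argued against by the nlp2-2 median of -0.74 against Col-4. Stress of single wild-type samples alone is argued against as all 6 of 6 wild-type shoot libraries lay above every library of their own nlp2 single mutant (4.43 to 4.98 against 2.23 to 3.56). This separation follows in large part from the calls in the same libraries. Stress shared by all samples of a wild type would give it alike. A different time of harvest would move clock genes, and the lowest number of called clock members was 0 of 13 by edgeR in nlp2-2, nlp2-3 and nlp7-1 (2, 1 and 3 with an unadjusted p under 0.05, and 0, 0 and 1 by DESeq2), with 3 in the double mutant. Microbes on the plants were not measured, so a lower load in the mutants and a difference of parental line stay open. So does a difference between pots, since pots that each held 1 genotype would separate the libraries alike.

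Genes near an insertion were not clearly enriched. Within 1 Mb of NLP7, 39 of 439 root genes were called in nlp7-1, 8.88% against 7.92% elsewhere (Fisher exact test, two-sided, p = 0.475). Within 1 Mb of NLP2, 42 of 459 were in nlp2-3, 9.15% against 6.79% (Fisher exact test, two-sided, p = 0.0605). Differences linked to the insertion cannot be told apart from effects of the mutation by these tests, since a p above 0.05 does not exclude them.

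Splits of 6 libraries into 3 and 3 number 10, too few for a share under 0.05, and in each pair comparison the real split alone, 1 of 10, called as many genes. The real count and the highest other in roots were 1458 and 0 for nlp2-2, 1401 and 0 for nlp2-3, 1627 and 1 for nlp7-1, 5154 and 1 for the double mutant and 8 and 0 for Col-4 against Col-0. They were 1762 and 2 for nlp2-2 against Col-0, 1334 and 53 for the double mutant against nlp7-1 and 1326 and 1 against nlp2-3. In shoots they were 586 and 41, 1110 and 0, 1870 and 0, 5948 and 0, 152 and 2, 1360 and 0, 1530 and 0 and 5081 and 0 in the same order. The shoot interaction (719, highest other 2) was matched by 1 of 25 splits, the real one, so the share is under 0.05. These splits moved libraries between genotypes, so they do not test the interaction apart from other effects of genotype. The root interaction (49) was matched by 4 of 25, with 1423 genes in the highest. Since such splits can hold genotype effects, they neither exclude chance for it nor speak for it.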
